A study of Mus musculus with 4 samples.

How the data were processed

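RNA was measured in LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive bone marrow cells, the fraction that holds the haematopoietic stem cells and multipotent progenitors) sorted from Mll5-deficient (KO) and wild-type (WT) mice. Per the labels' protocols, Cy3-labelled cRNA was made from 320 ng of total RNA with a linear amplification kit and hybridised for 14 h, in 1 colour, to Agilent whole mouse genome arrays, and raw intensities were extracted with Agilent Feature Extraction 9.1, per the submitters' processing notes. The values used here are the log2 brightness values deposited by the authors, 1 per probe and array. They are taken as log2 from their range, 5.25 to 18.65, since no label states the scale. The background correction, the normalization method and any filter on probes are not given in the sources used here. The sorted values of each other array differed from those of WT replicate 1 by at most 0.037, as after a quantile normalization. The array medians lay between 6.807 and 6.814, so the values were used without further scaling. Such a normalization removes any change that all transcripts share.

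The table has 41174 rows and no missing value, and names its rows only by the numbers 1 to 41174. Row number followed the mean difference between KO and WT (Spearman's rho = 0.99998), and the largest step against that order was 0.002 on the log2 scale. The number is therefore a position in a list sorted by that difference, and the files do not pair it with a probe or gene. The probes are accordingly reported without gene names or genome positions, and a row number tells nothing beyond that position. The 25 gene lists fixed before the data were examined, the sex-linked check genes and the targeted gene itself were not analysed here, because each needs gene names.

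Each sample's group was taken from its title. KO was compared with WT over all 4 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, without a replicate term), and p-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Probes were tested if their mean over the 4 arrays reached the 40th percentile of all probes, a log2 brightness of 6.156. This left 24704 probes. The planned requirement of a gene symbol and the planned count of distinct genes were replaced by the probe. An error is the SD over the 2 pools of a genotype or the standard error (SE) of the limma fit. Individual probes were chosen by a rule fixed before the data were examined, namely the smallest unadjusted p among probes whose KO and WT values did not overlap when too few passed the threshold. That rule would have filled each direction to 8 probes, of which only the first 2 are given by number because the numbers are not gene identifiers.

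The test was run on simulated data drawn from the real probe means and the fitted variance prior, with 5 simulations per setting over 24704 probes. Among 200 altered probes it recovered 84.6% of 2-fold changes and 99.4% of 4-fold changes. Among 20 altered probes it recovered 5% of 2-fold changes and 97% of 4-fold changes. The simulated arrays had independent errors, and the altered probes of a setting all changed by the same fold, so these rates may not hold for the real arrays. Alternatives covered the scaling of arrays, the brightness filter, an offset for low values, the variance model, the threshold, a replicate term and leaving out each array. No detection flag or scan batch is in the table, and the number of arrays limits the precision.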

Results

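Expression was profiled in LSK cells, the stem and progenitor fraction of mouse bone marrow, to ask how loss of Mll5 alters their transcripts. Mll5, listed as Kmt2e in current mouse annotation, encodes a SET-domain protein of the mixed-lineage leukaemia family. The mice were 8 weeks old, and the wild-type animals were sex-matched littermates of the Mll5-deficient animals. Each array held RNA from 1 pool of 6 mice, with 2 pools per genotype, so the replicate spread is that between pools. All 4 arrays gave a value for each of 41174 probes. The deposited values were log2 brightness, with medians of 6.814 and 6.807 in WT replicates 1 and 2 and 6.811 in each KO replicate. The level of Mll5 itself was not analysed here because the probes carry no gene names, so the genotype labels were not checked against it.

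By SD, the transcript profiles of Mll5-deficient and wild-type LSK cells differed about as much as those of replicate pools of a single genotype. By median absolute deviation and 2-fold counts, pairs of different genotype and different replicate number differed slightly more than pairs within a genotype. Over the 24704 probes tested, the difference between a KO and a WT array had a mean SD of 0.227 on the log2 scale (range 0.189 to 0.264, 4 pairs of arrays). The corresponding mean within a genotype was 0.230 (2 pairs), with 0.220 between the WT pools and 0.240 between the KO pools. Both pairs within a genotype joined different replicate numbers. The mean between genotypes, here and by brightness below, also holds pairs of the same number and is not a like comparison. The KO and WT arrays of different number gave 0.264 and 0.229, and those of the same number gave 0.189 and 0.226. A few extreme probes, such as those of KO replicate 2 described below, can raise an SD. The median absolute deviation, scaled to match an SD, is hardly moved by them. It was 0.166 and 0.163 for the KO and WT arrays of different number, 0.157 for the WT pair and 0.159 for the KO pair. Between 51 and 162 probes lay at least 2-fold apart in the pairs of different genotype, with 162 and 137 in those of different replicate number, against 124 in the WT pair and 125 in the KO pair. Pearson's r across probes, which are not independent replicates, ranged from 0.9947 for WT replicate 1 with KO replicate 2 to 0.9973 for WT replicate 1 with KO replicate 1. The spread was widest at intermediate brightness, with an SD of 0.29 within and 0.291 between genotypes in the decile of probes with a mean log2 brightness of 8.554. In the brightest decile these values were 0.166 and 0.165. The extreme probes of KO replicate 2 can raise the SD of the decile they fall in. The peak at intermediate brightness may therefore rest partly on them, and it was not computed without them.

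**Figure D1:**
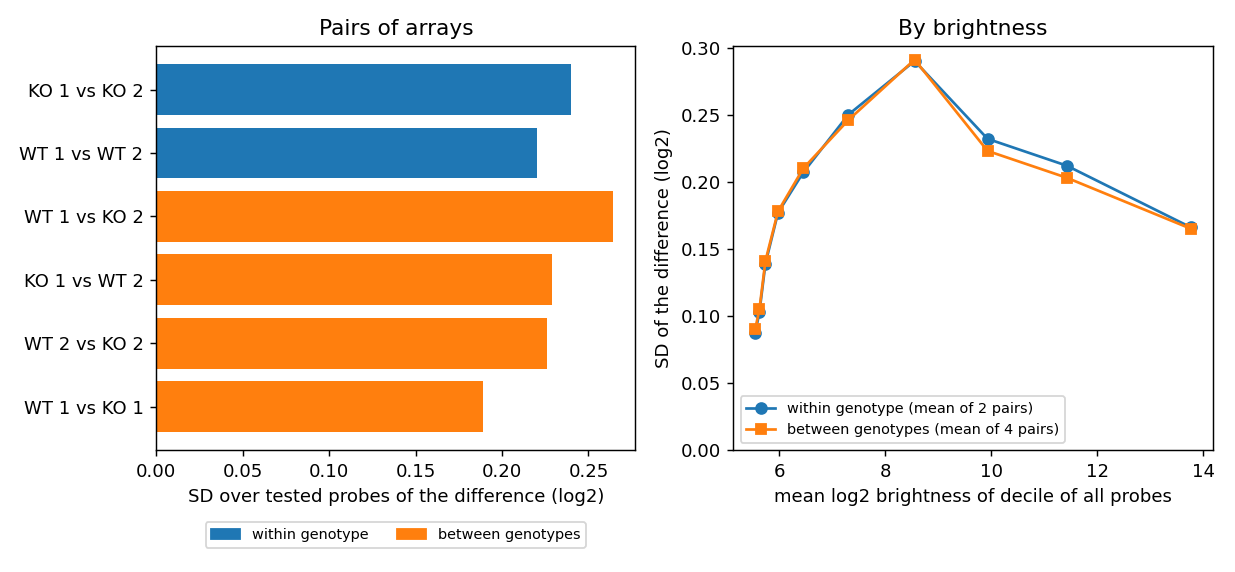
Left, SD over the 24704 tested probes of the log2 difference between 2 arrays, 1 bar per pair of arrays (KO and WT with their replicate number). Right, the same SD averaged over the 2 pairs within a genotype and the 4 pairs between genotypes, for each brightness decile of all 41174 probes. The pairs within a genotype, 0.220 and 0.240, lie inside the range of the pairs between genotypes, 0.189 to 0.264. Both pairs within a genotype join different replicate numbers. The KO and WT pairs that do so gave 0.264 and 0.229, and the averages on the right also hold the pairs of the same number.

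No probe was called higher or lower in Mll5-deficient cells by limma, fitted without a replicate term, at a Benjamini-Hochberg adjusted p of 0.05, and the lowest adjusted p was 0.311. An unadjusted limma p under 0.05 was reached by 1290 probes, 629 with a higher and 661 with a lower KO mean. Independent array errors would give 1235.2 by chance. The limma fit gave 2059 such probes when the arrays were split by replicate number instead. It gave 390 when WT replicate 1 and KO replicate 2 were set against the other arrays, so 1235.2 is no firm reference here. An ordinary linear model per probe called 0 probes, with 1366 at an unadjusted p under 0.05. With 2 residual degrees of freedom it could hardly have called any, so its 0 has little weight. Even probe 41171, with the smallest limma p, had an adjusted p of 0.888 in that model. The KO and WT values did not overlap in 32.4% of probes, and chance gives 33.3% for 2 samples against 2. The split by replicate number gave 38.3%, and that with WT replicate 1 and KO replicate 2 together gave 28%. When WT replicate 1 was left out 2 probes were called, both lower in KO, and when KO replicate 1 was left out 3 were called, all higher. The count depended most on a replicate term: with the replicate number as a block, which the labels do not tie to a shared litter or day, limma called 96 probes. That fit leaves fewer than the 2 residual degrees of freedom per probe of the main fit. Its p-values therefore lean on the spread shared over probes, and its rate of false calls was not simulated.

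The estimated differences were small for most probes. The KO mean lay within 1.2-fold of the WT mean for 93.5% of the tested probes, and the 95% confidence interval of the difference, not adjusted for the number of probes, lay within 2-fold in either direction for 24347 of them (98.6%). The tested probes reached down to a log2 brightness of 6.156, and differences near the lower end of the scale could be understated. A mean at least 2-fold higher in KO was measured for 14 probes and a mean at least 2-fold lower for 16. The values of the genotypes did not overlap in 5 of the former and 15 of the latter. None of these differences passed the limma test without a replicate term.

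The probes with the smallest p-values are given as measured values, none of which passed the threshold without a replicate term. Probe 41171 read 5.69 ± 0.18 in WT and 8.71 ± 0.59 in KO (log2 brightness, SD, n = 2 pools each), a limma difference of 3.02 (SE 0.264, adjusted p = 0.311). Its WT mean lay at the 22nd percentile of all probes and its KO mean at percentile 66.1. Probe 41170 had a similar profile, with 5.83 ± 0.11 in WT and 8.48 ± 0.56 in KO, and a limma difference of 2.65 (SE 0.247, adjusted p = 0.311). In both probes each KO pool exceeded each WT pool by more than 2 log2 units. Among probes with a lower KO mean, probe 32 read 11.68 ± 0.07 in WT and 10.90 ± 0.02 in KO, a limma difference of -0.78 (SE 0.084, adjusted p = 0.311). Probe 3 read 8.80 ± 0.10 in WT and 7.31 ± 0.30 in KO, a limma difference of -1.49 (SE 0.162, adjusted p = 0.311). With the replicate number as a block all 4 probes passed, with limma adjusted p-values from 0.000189 to 0.0118, in a fit that was not simulated. The 8 probes with the smallest p-values in each direction had differences of 0.52 to 3.02 log2 units where KO was higher and 0.67 to 1.52 log2 units in size where KO was lower.

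**Figure D2:**
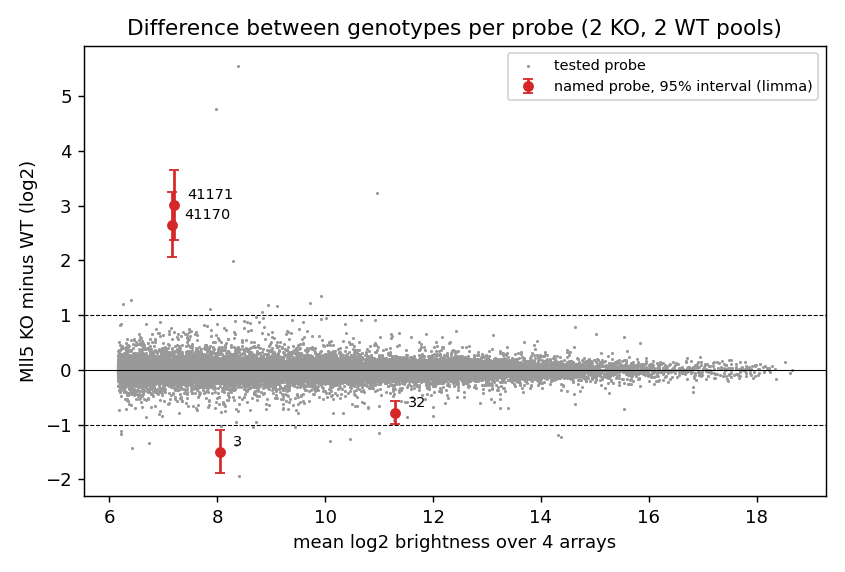
Difference between the KO and WT means (log2, vertical axis) against the mean log2 brightness over the 4 arrays (horizontal axis) for the 24704 tested probes (grey), with 2 pools per genotype. Red points with 95% limma confidence intervals are the 4 probes given by number, and the dashed lines mark 2-fold. A mean difference of at least 2-fold was measured for 14 probes above and 16 below.

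On simulated arrays with the same probe means and fitted error, the fit recovered 97% of 4-fold changes and 5% of 2-fold changes when 20 of 24704 probes were altered. Most 2-fold changes of so few probes were therefore missed in the simulation by this fit, which has no replicate term. The altered probes all changed by the same fold and the errors were independent, whereas the real arrays differed by replicate number. The recovery of 4-fold changes may therefore not hold for the real arrays. There, probes 41171 and 41170, with measured differences of 8.11-fold and 6.29-fold, were not called.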

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

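No probe was called under 15 of 18 alternatives, but several of these could hardly call any. The looser threshold of 0.10 and the added 2-fold limit could not, as the lowest adjusted p was 0.311. The ordinary linear model had little power. The rescalings acted on arrays that already shared nearly 1 distribution, and array quality weights were nearly equal (0.993 to 1.007). An unadjusted p under 0.05 was reached by 852 to 2162 probes over all 18. The numbers tested differed, with 16471 for the count of 852 and 24704 for that of 2162. Of the 18, array quality weights and cyclic loess were chosen after seeing the data. With the replicate number as a block, limma called 96 probes, 45 higher and 51 lower in KO, with differences of 0.41 to 3.02 log2 units in size, and 18 of them reached 2-fold. The rate of false calls of that fit was not simulated. The labels do not say that a replicate number marks a shared litter, day or slide, and 2 numbers are too few to settle it. Replicate 2 minus 1 correlated across probes between WT and KO (Pearson's r = 0.338, Spearman's rho = 0.221), a hint outside the design. Leaving out each array in turn gave 0 to 3 called probes, with 0 to 3 higher and 0 to 2 lower in KO. The 2 lower probes came without WT replicate 1 and the 3 higher ones without KO replicate 1, the single array left in a group being assumed to vary like the others. The 4 probes given by number kept their direction in all 62 values computed. They were chosen for values without overlap and most alternatives left the difference almost unchanged, so the constant direction is no independent check. These probes passed the threshold in 4 of the 62 values, all with the block (lowest limma adjusted p 0.000189). The targeted gene, gene lists and count per gene need gene names and were not tested. Detection flags were not used, so differences near the lower end of the scale could be understated.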

Other observations

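The tests on how the arrays split and on single spots were chosen after the result was seen, and that on RNA of other cells was written down before.

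The arrays differed more by replicate number than by genotype. The 4 arrays can be split into 2 and 2 in 3 ways. Splitting by replicate number gave 38 called probes in limma at an adjusted p of 0.05, against 0 for genotype and 0 for the crossed split, and 3 splits are too few for a share under 0.05. At least 2-fold differences without overlap were found in 90 probes by replicate number, 20 by genotype and 3 in the crossed split. After cyclic loess, a further scaling by brightness, limma again called 38 probes by replicate number, against 0 for genotype and 0 for the crossed split. The deposited values were already brought to nearly one distribution, so this is only a weak test of an effect of brightness on this split. Shared handling of same-numbered pools (38 probes, no recorded batch) and differences between the groups of mice in each pool remain open as candidate explanations and cannot be told apart.

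KO replicate 2 held more probes that were far brighter in 1 array than in the rest than any of the other arrays did. In that array 40 probes lay at least 2-fold above every other array, against 13 in WT replicate 1, 24 in WT replicate 2 and 7 in KO replicate 1. The 3 highest read 16.62, 15.11 and 16.11 in KO replicate 2, and their highest value in any other array was 5.68, 5.60 and 9.38. These 3 were the probes called when KO replicate 1 was left out. The 3 mean differences they give therefore rest on 1 pool.

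The authors' processing steps before deposition are not given in the sources used here, and their part in these 40 probes was not tested. For the 37 probes other than the 3 highest, independent defects of single spots are argued against. The median over these probes of WT replicate 2 minus WT replicate 1 was 0.717 log2 units. It lay outside the central 95% of 10000 random lists matched on WT brightness (-0.067 to 0.058). The lists were not matched on variability, so that range may be too narrow for these probes. Of the 37, 35 were higher in WT replicate 2 than in WT replicate 1. KO replicate 1 also exceeded WT replicate 1 in 32 of the 37, and WT replicate 1 was the lowest of the 4 arrays in 32, so these probes varied over several arrays and not in KO replicate 2 alone. For the 3 highest the same difference was -0.015, and 3 probes are too few to test, so a spot defect stays open there. RNA of other cells, in that pool or in unequal amounts over the pools, may also account for the 40 probes, but the probes carry no gene names and no marker could be examined. Differences between the mice of the pools are open and untested.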
